A study of Coturnix japonica with 54 samples.

How the data were processed

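Pituitary glands of 54 male Japanese quail (Coturnix japonica) were sequenced 1 library per bird, with 6 birds at each of 9 photoperiods. Per the labels' protocols, polyadenylated RNA was converted to cDNA and barcoded with an Oxford Nanopore direct cDNA kit for long-read sequencing. The day length was lowered from 16 h to 8 h of light and raised again in steps of 2 h, with 2 weeks at each step. Groups are named by hours of light and the direction of change, with a for the autumn-like decline and v for the spring-like increase. Groups were taken from the treatment label of each bird, and all birds had a group. Replicate numbers within a photoperiod follow the order of deposition, which at 16Lv differs from the order of bird numbers, and pair no birds across photoperiods. The rank of a bird is that of its own number within its photoperiod.

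The deposited table of estimated counts holds 40282 transcript rows. Per the submitters' processing notes, minimap2 2.17, Salmon 0.14.2 and edgeR 3.24.3 were used, and their roles and the genome build are not given in the sources used here. The deposited CPM table was checked against the counts and behaves as a normalised signal per gene. In each bird it equalled the gene's summed count divided by the library total times a factor of 0.559 to 3.06, per 1000000, so that its columns summed to between 327092 and 1790364. All 40282 transcripts matched the gene table of the Coturnix japonica 2.1 assembly by accession, with equal symbols, and no coordinates are printed because no build is named.

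Estimated counts were rounded and summed over the transcripts of each gene. Of 9983 values of genes with 2 transcripts and 3 or more counts, 5354 (53.6%) were equal on both transcripts within 0.01. A read therefore appears to be entered on several transcripts of a gene, and summed counts were 2.08 times the counts of the largest transcript. Totals below are sums of estimated counts and not numbers of molecules, and counting floors of 3 counts cover counting error only and are lenient where a read was entered more than once.

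Library totals ranged from 4834 to 156500 (median 39687), and genes with a count above 0 ranged from 544 to 9757 per library. With these totals 826 of 16442 genes passed the filter on low counts, so that most genes were not tested in the main test. On simulated data for 8L against 16La, with 200 of 826 summed genes changed, the test called 27.3% of genes changed 4-fold and 64.3% of genes changed 16-fold. With 105 of 210 largest-transcript genes changed, it called 98.7% and 100% of such genes. With 200 of 1460 genes changed, by the largest transcript and a minimum count of 3, it called 65.3% and 91%. False calls per simulation were 4.67, 4.67 and 7 in that order. The simulated share of changed genes differed between countings and exceeded the share called in the data, which eases the adjusted threshold. These percentages are therefore not the sensitivity of the real tests and do not rank the countings.

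The main test was edgeR 4.0.16's quasi-likelihood F-test (robust fit, TMM scaling, filterByExpr with a minimum count of 10) in R 4.3.3, with all 54 birds, 1 mean per photoperiod, no covariate and 45 residual degrees of freedom. P values were adjusted by Benjamini-Hochberg over the 826 genes at a threshold of 0.05. Standard errors are the fold change divided by the square root of F. Comparisons were any difference among photoperiods, the 3 comparisons of the cycle's end points, a linear contrast on light hours, the difference of the spring and autumn slopes, the 3 matched day lengths, and the 8 successive steps. Levels are CPM of the library's summed total, as mean and SD over birds. Gene lists were tested with limma 3.58.1's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, for lists with 3 or more tested genes.

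Before the data were examined, gene lists, designs, alternatives and the rule for named genes were fixed. The rule named all measured pituitary hormones with OPN5, DIO2, DIO3, EYA3 and MTNR1A, up to 10 genes with a symbol in each direction by p for the main comparisons, up to 5 for slopes, matched day lengths and steps, and 4 members of each list described. LOC107319226 and LOC107323085 have no symbol and fall outside it, and were chosen after its values were seen. The alternatives fixed then were another scaling, no filter, DESeq2 1.42.0, fits of 2 groups only, limma on log2 of deposited CPM plus 1, the log2 total as a covariate, leaving out libraries under 13229 counts, and transcript rows. Chosen after seeing the data were the largest transcript count per gene, the same with a minimum count of 3, the rank of the bird number as a block, leaving out the highest-numbered birds, the 9 libraries with under 2000 genes detected or the 2 genes with the most counts, and leaving out each library in turn, also with the largest transcript and a minimum count of 3. For each count of genes, 100 splits of the birds were drawn. An earlier draw of 40 splits had been run, and the closing section gives its values where they differed. Exact permutation tests on CPM and the correlations within photoperiods were also added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

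GH, LHB, MTNR1A and the mitochondrially encoded genes were not analysed here. Among fixed lists, those for gonadotrophs, thyrotrophs, photoreceptors, the clock, lactotrophs, somatotrophs, corticotrophs, stem-like cells, brain, blood, endothelium, matrix, immune cells, proliferation, immediate early genes, protein folding and DNA methylation had fewer than 3 genes past the filter and were not tested on summed counts.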

Results

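Pituitary transcriptomes were measured in 54 male Japanese quail, a long-day breeding bird, at 9 points of a simulated annual cycle of day length, with 6 birds at each point. Libraries were shallow and uneven, with a mean total of 67286 ± 36153 counts (SD, n = 24) over the 4 photoperiods of the autumn-like arm, 41273 ± 7982 (SD, n = 6) at 8L and 32931 ± 23266 (SD, n = 24) over the 4 photoperiods of the spring-like arm. ACOT9, an acyl-CoA thioesterase, took between 11.2% and 68.6% of the summed counts of a library. Its 7 transcripts differed by at most 1 count in any bird, and by largest-transcript counts its share was between 3.23% and 27.4%. In 6 of the 9 photoperiods the bird with the highest number had the fewest genes detected, and these 9 birds had a mean of 1802 genes against 5184 in the others.

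**Figure D1:**
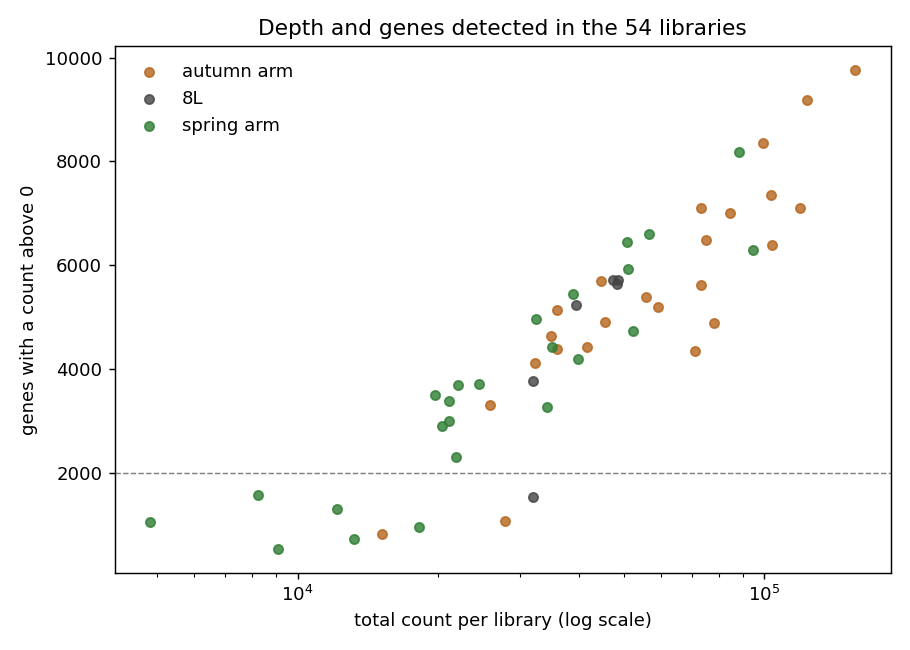
Each point is 1 of the 54 libraries, with its total count on a log scale against the number of genes with a count above 0, coloured by arm of the cycle. The dashed line marks 2000 genes, and 9 libraries lie under it.

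The first question was which transcripts differed anywhere in the cycle. Of the 826 genes tested, 4 were past the threshold. These were CGA, the alpha subunit shared by the glycoprotein hormones, FSHB, the beta subunit of follicle-stimulating hormone, PRL, the gene of prolactin, and LOC107319226, a protein-coding locus between BBS2 and NUP93. Adjusted p values of edgeR's quasi-likelihood test were 5.36e-10 for CGA, 7.61e-07 for FSHB and for LOC107319226, and 2.24e-06 for PRL. POMC, the precursor of adrenocorticotropin, was abundant at every photoperiod and did not pass (adjusted p = 1.00).

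FSHB was undetected on the shortest day and higher on long days, and its highest mean was at 12Lv in the spring arm, with a lower mean at 14Lv. Its mean was 202 ± 176 CPM at 16La, 420 ± 256 at 14La, 30.1 ± 36.8 at 12La and 12.7 ± 15.2 at 10La (SD, n = 6 each). All 6 birds at 8L had 0 counts of 247636, which allows up to 12.1 CPM over the group. On the return it was 114 ± 139 CPM at 10Lv, 896 ± 523 at 12Lv, 148 ± 79.02 at 14Lv and 293 ± 203 at 16Lv (SD, n = 6 each).

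CGA was also high on long days, at a higher level, with its lowest mean at 12La and its highest at 12Lv. The place of the highest mean depends on the scaling, since in deposited CPM it was at 14La (10170, against 8384 at 12Lv). It fell from 6264 ± 2066 CPM at 16La and 7890 ± 3088 at 14La to 1033 ± 338 at 12La, and stood at 1190 ± 650 at 10La and 1405 ± 348 at 8L (SD, n = 6 each). In the spring arm the means were 3246 ± 1025 CPM at 10Lv, 7957 ± 3760 at 12Lv, 6716 ± 3215 at 14Lv and 5224 ± 3922 at 16Lv (SD, n = 6 each). PRL was 17641 ± 8843 CPM at 16La, 22622 ± 6140 at 14La, 9840 ± 7499 at 12La, 4581 ± 2375 at 10La and 3179 ± 1573 at 8L (SD, n = 6 each). It was then 4124 ± 2035 CPM at 10Lv, 11774 ± 5252 at 12Lv, 17531 ± 6864 at 14Lv and 11428 ± 9713 at 16Lv (SD, n = 6 each). LOC107319226 was 440 ± 186 CPM at 16La and 571 ± 188 at 14La, lay between 28.4 and 31.5 CPM on average at 12La, 10La, 8L and 10Lv, and was 760 ± 563 at 12Lv, 297 ± 96.5 at 14Lv and 231 ± 170 at 16Lv (SD, n = 6 each).

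**Figure D2:**
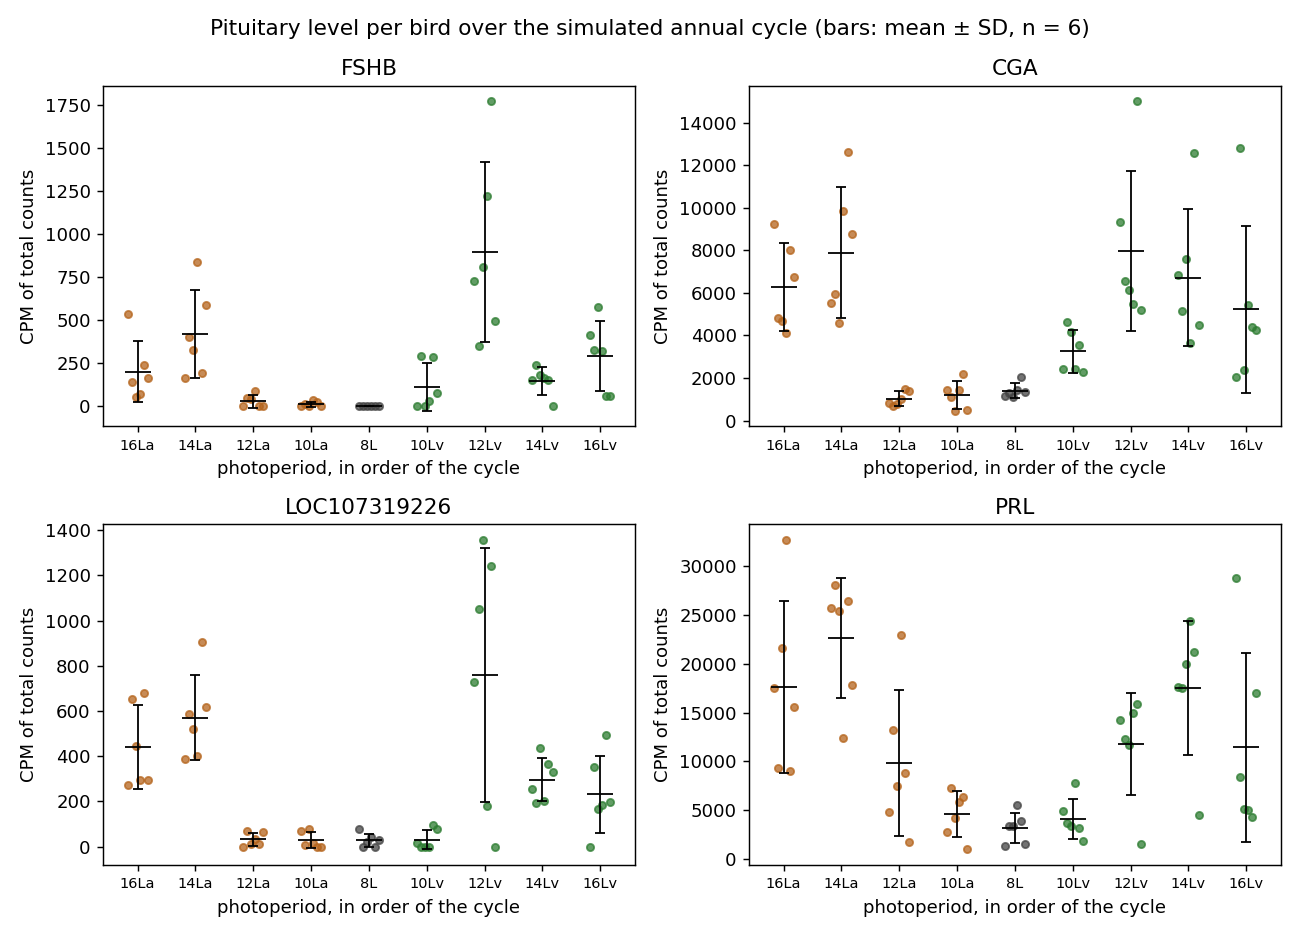
Each point is the level of 1 bird in CPM of its total count, for FSHB, CGA, LOC107319226 and PRL at the 9 photoperiods in the order of the cycle, and bars are the mean and SD of 6 birds. FSHB is at 0 in all 6 birds at 8L, and CGA averages 1033 CPM at 12La against 7957 at 12Lv.

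POMC lay between 9770 ± 2656 CPM at 14La and 26174 ± 23041 at 16Lv (SD, n = 6 each). TSHB, the beta subunit of thyroid-stimulating hormone, was below the filter with 163 counts in 42 birds, and its means ran from 36.3 ± 28.2 CPM at 14La to 106 ± 103 at 10Lv (SD, n = 6 each). With the largest transcript count per gene and a minimum count of 3, TSHB had a slope of -0.14 ± 0.06 per hour of light on the log2 scale (SE), opposite to CGA, FSHB and PRL, with an adjusted p of 0.602 over all genes and 0.0206 adjusted over the list alone. DIO2, the deiodinase that activates thyroid hormone, had 76 counts and was seen in 6 of 6 birds at 8L (54.4 ± 23.1 CPM; SD, n = 6) and in 3 of 6 at 16La (10.7 ± 12.7 CPM; SD, n = 6), with 27.4 ± 37.5 CPM at 10La, 34.4 ± 26.9 at 10Lv and 41.1 ± 33.5 at 14Lv (SD, n = 6 each). EYA3, a transcriptional coactivator, had 95 counts in 22 birds. OPN5, a deep-brain photopigment, and DIO3, the deiodinase that inactivates thyroid hormone, had 2 counts each, so that no difference in either was detectable at this depth.

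The end of the autumn-like decline was compared with its start. At 8L, CGA was lower than at 16La by a log2 fold change of -2.19 ± 0.37 (SE), PRL by -2.58 ± 0.45 and LOC107319226 by -3.86 ± 0.84. FSHB at 16La, as the group's counts over the group's total, was 16.6 times the floor of 3 counts over the 8L birds. This ratio leaves out counting error and the spread of birds at 16La. The ratio was 11.1 without 16La replicate 1, which held 39 of the 88 counts at 16La, and 13.4 without 8L replicate 2. For each of these 4 genes all 6 birds at 8L lay below every bird at 16La. Adjusted p values were 0.000188 for CGA, 0.000320 for PRL, 0.000334 for FSHB and 0.00591 for LOC107319226, and no gene was higher at 8L with edgeR. Higher at 8L were 3 genes with the log2 total count as a covariate, 1 with DESeq2, 1 with the largest transcript and a minimum count of 3, 1 without the libraries of low detection and 8 without a filter. NELL2, a secreted neural protein, had a log2 fold change of -2.09 ± 0.71 (SE; adjusted p = 0.407) and was lower at 8L with DESeq2 (adjusted p = 0.0288), in transcript rows (0.00375) and with the largest transcript (0.00636, and 0.0407 with a minimum count of 3). In the fit of the 12 birds alone FSHB had an adjusted p of 0.0771, and LOC107319226 had 0.159 with limma and 0.0615 without a filter.

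Of the 4 pituitary hormone genes tested, 3 fell at 8L (CGA, PRL and FSHB), adjusted over the list alone and over all genes, and POMC had a log2 fold change of 0.17 ± 0.53 (SE). The list as a whole was lower by camera (adjusted p = 1.74e-14, and 7.86e-09 with an estimated correlation). None of the 72 cytosolic ribosomal protein genes passed over all genes or adjusted over the list alone, and their median log2 fold change was 0.09. Camera placed them higher (adjusted p = 0.0308), which was not held with an estimated correlation (adjusted p = 0.595). None of 7 secretory granule genes passed, with CHGB at -0.85 ± 0.53 and SCG3 at -0.52 ± 0.53 (log2 fold change ± SE). None of 3 steroid and thyroid hormone receptors passed, with ESR1 at -0.68 ± 1.02, nor did any of 5 nuclear-encoded oxidative phosphorylation genes, with NDUFB3 at -2.02 ± 1.00.

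The spring-like increase was compared with the shortest day. At 16Lv, FSHB over the group's total was 17.3 times the floor at 8L, and CGA was higher than at 8L by a log2 fold change of 1.73 ± 0.36 (SE). The ratio for FSHB leaves out counting error and the spread of birds at 16Lv. It was 13.9 without 8L replicate 2 and 14.2 without 16Lv replicate 2. FSHB was above 0 in all 6 birds at 16Lv, and CGA was above every 8L bird in 5 of 6. Adjusted p values were 0.000523 for FSHB and 0.00613 for CGA. PRL had a log2 fold change of 1.63 ± 0.44 and LOC107319226 of 2.87 ± 0.83 (SE), with adjusted p values of 0.112 and 0.181. Both passed with the largest transcript count per gene (adjusted p = 0.0113 and 0.00121), with DESeq2 (0.00645 for both), in transcript rows (0.0174 and 0.00137) and in exact permutation tests on CPM (0.0395 for both). PRL also passed with the log2 total as a covariate (0.0122) and with the bird rank block (0.0171), and LOC107319226 with a minimum count of 3 (0.0236) and without the libraries of low detection (0.0475). The call of CGA was lost without 8L replicate 1, 2, 3 or 4 or without 16Lv replicate 2 (highest adjusted p = 0.115), and neither gene passed in the fit of the 12 birds alone (adjusted p = 0.385 for FSHB and 0.434 for CGA). The call of CGA was also lost with limma (adjusted p = 0.515) and without a filter (adjusted p = 0.209).

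Of the 4 pituitary hormone genes, 2 rose at 16Lv over all genes and 3 adjusted over the list alone, the third being PRL. Camera gave an adjusted p of 2.11e-12, and 5.26e-08 with an estimated correlation. No member of the other 4 lists passed, and their camera adjusted p values ran from 0.144 to 0.786.

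The same day length was compared before and after the cycle. No gene passed at 16Lv against 16La with edgeR, 47 genes had an unadjusted p under 0.05 where 41.3 are expected by chance, DESeq2 called 0 and limma called 4. At an unadjusted p under 0.05, DESeq2 had 36 genes and limma 153. FSHB had a log2 fold change of 0.35 ± 0.78, CGA of -0.46 ± 0.35 and PRL of -0.94 ± 0.43 (SE). With the largest transcript and a minimum count of 3, PRL was lower at 16Lv by -1.25 ± 0.44 (log2 fold change ± SE), with an adjusted p of 0.0232 adjusted over the list alone and 0.706 over all genes. These values do not show that the long-day groups were alike. The 72 ribosomal protein genes, none of which passed, were placed higher by camera (adjusted p = 0.00685, and 0.538 with an estimated correlation), while their median log2 fold change was -0.05. The median over all genes in this comparison was -0.28. Camera ranks a list against the other genes, so a list above that median can be placed higher.

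Over all 54 birds, CGA, PRL, FSHB, LOC107319226 and NELL2 were higher on longer days. The slopes per hour of light on the log2 scale were 0.29 ± 0.03 for CGA, 0.31 ± 0.04 for PRL, 0.67 ± 0.09 for FSHB, 0.55 ± 0.08 for LOC107319226 and 0.26 ± 0.06 for NELL2 (SE). Adjusted p values were 8.95e-09, 2.44e-07, 1.66e-06, 1.59e-06 and 0.0266 in that order. No gene had a negative slope past the threshold with edgeR on summed counts. With the log2 total as a covariate 1 gene did, with the largest transcript and a minimum count of 3 there were 2, and without a filter 21. The call of NELL2 was lost without 16La replicate 2, 8L replicate 2, 8L replicate 6 or 16Lv replicate 4 (highest adjusted p = 0.0899), without a filter (adjusted p = 0.180) and in limma (adjusted p = 1.00). The pituitary hormone list had 3 of 4 genes with a positive slope past the threshold, adjusted over the list alone and over all genes (camera adjusted p = 6.18e-21, and 1.25e-11 with an estimated correlation), and POMC had a slope of -0.03 ± 0.05 (SE).

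The 2 arms were compared for their dependence on the direction of change. No gene had a different slope in spring than in autumn with edgeR, with 43 genes at an unadjusted p under 0.05, and DESeq2 and limma called 0. At an unadjusted p under 0.05, DESeq2 had 28 genes and limma 124. CGA had a slope difference of -0.13 ± 0.04 per hour on the log2 scale (SE; adjusted p = 0.289).

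At a matched day length of 12 h, CGA, FSHB and LOC107319226 were higher in the spring arm. The log2 fold change of 12Lv against 12La was 2.79 ± 0.38 for CGA, 4.55 ± 0.88 for FSHB and 4.44 ± 0.86 for LOC107319226 (SE). All 6 birds at 12Lv were above every bird at 12La for CGA and FSHB, and 5 of 6 for LOC107319226. Adjusted p values were 1.16e-06 for CGA and 0.00161 for FSHB and LOC107319226. PRL did not pass, with a log2 fold change of 0.12 ± 0.43 (SE; adjusted p = 0.995). List tests at 12 h were added after the data were seen, with the largest transcript and a minimum count of 3. The list of fibroblast and matrix genes was lower at 12Lv than at 12La by camera (adjusted p = 3.21e-06, and 0.00226 with an estimated correlation). Camera placed the pituitary hormones higher (adjusted p = 3.01e-09, and 0.000288 with an estimated correlation). Of these 5 genes 2 passed, CGA and FSHB, and the median log2 fold change was -0.01. The list result thus rests on genes already called at 12 h and does not show higher hormones as a whole. Protein folding was placed higher too (0.0141, but 0.338 with an estimated correlation). Of the 4 tested matrix genes, COL1A2, a collagen, and SPARC, a matrix protein, passed (adjusted p = 0.0118 and 0.0287). COL3A1 did so adjusted over the list alone (0.00258), and DCN had a log2 fold change of -0.28 ± 0.57 (SE). COL1A2 averaged 332 ± 399 CPM of largest-transcript counts at 12La (SD, n = 6) and 177 ± 134 without 12La replicate 1 (SD, n = 5), against 67.02 ± 77.1 at 12Lv (SD, n = 6). Its call was lost without 12La replicate 1 or 12Lv replicate 3 or 5 (highest adjusted p = 0.240), and that of SPARC without 12La replicate 3 or 4 or 12Lv replicate 1, 2, 3, 4 or 6 (highest adjusted p = 0.851). On summed counts SPARC did not pass (adjusted p = 0.674). MBP, a myelin protein, had 287 counts in 12La replicate 5 and at most 8 in each of the other 12La birds. With limma LOC107319226 had an adjusted p of 0.779.

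No gene passed at 14 h or at 10 h with edgeR, and 21 and 40 genes had an unadjusted p under 0.05. DESeq2 called 0 at 14 h and 1 at 10 h, and limma called 0 at both. At 10 h, CGA had a log2 fold change of 1.30 ± 0.36 (SE) with an adjusted p of 0.270. It passed with the largest transcript count (adjusted p = 0.0417) and in an exact permutation test on CPM (adjusted p = 0.00866). CGA was also the gene called with DESeq2, RLE scaling and the bird rank block. It did not pass with the largest transcript and a minimum count of 3, with limma or in the fit of the 12 birds alone. FSHB had a log2 fold change of -1.74 ± 0.78 at 14 h (SE; adjusted p = 0.995). In exact permutation tests on CPM, FSHB and LOC107319226 were lower at 14Lv than at 14La, with means of 148 against 420 and of 297 against 571 CPM (adjusted p = 0.0433 and 0.0306).

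Successive steps of 2 h placed the fall between 14 h and 12 h of light. From 14La to 12La, CGA fell by 2.89 ± 0.38, LOC107319226 fell by 4.27 ± 0.85 and FSHB fell by 3.62 ± 0.85 on the log2 scale (SE), with all 6 birds at 12La below every bird at 14La for each. Adjusted p values were 4.81e-07, 0.00307 and 0.0290. The call of FSHB was lost without any 1 of 7 birds, namely 14La replicates 4 and 6 and 12La replicates 1, 2, 3, 5 and 6 (highest adjusted p = 0.108), without the 9 libraries of low detection (adjusted p = 0.0983), without the highest-numbered birds (0.262), in the fit of the 12 birds (0.191), with limma (0.130) and without a filter (0.0891). The call of LOC107319226 was lost with limma (adjusted p = 0.423). With the largest transcript and a minimum count of 3, the list of fibroblast and matrix genes was higher at 12La than at 14La by camera (adjusted p = 0.00168), which was not held with an estimated correlation (adjusted p = 0.0503).

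In the spring arm, FSHB was past the threshold from 8L to 10Lv (adjusted p = 0.0264), and over the group's total at 10Lv it was 6.90 times the floor at 8L. This ratio leaves out counting error and the spread of birds at 10Lv. It was 4.49 without 10Lv replicate 2, 4.51 without replicate 5 and 10.4 without replicate 1. The call rested on 14 counts in 4 of 6 birds against 0 of 6 (Fisher's exact test, two-sided p = 0.0606). It was lost without 8L replicate 1, 2, 3, 4 or 5 or 10Lv replicate 2 or 5 (highest adjusted p = 0.142) and in 8 of the other alternatives. From 10Lv to 12Lv, LOC107319226 rose by a log2 fold change of 4.72 ± 0.91 (SE; adjusted p = 0.00352), and 5 of 6 birds at 12Lv lay above every bird at 10Lv. FSHB had a change of 3.14 ± 0.84 and CGA of 1.40 ± 0.36 (SE), with adjusted p values of 0.116 and 0.112. Both passed with the largest transcript count per gene (adjusted p = 9.99e-05 and 0.0419) and with DESeq2, FSHB also in transcript rows and with a minimum count of 3 (adjusted p = 0.00308), and CGA also with RLE scaling and the bird rank block. The rise of LOC107319226 had an adjusted p of 0.412 in the fit of 12 birds, 0.819 with limma and 0.0802 without a filter. No gene passed at the other 5 steps with edgeR. The numbers at an unadjusted p under 0.05 were 10 from 16La to 14La, 22 from 12La to 10La, 25 from 10La to 8L, 37 from 12Lv to 14Lv and 55 from 14Lv to 16Lv, and of these steps DESeq2 called 1 gene, at the last, and limma 0. From 12Lv to 14Lv, FSHB fell by 2.496 ± 0.52 and LOC107319226 fell by 1.59 ± 0.40 on the log2 scale with the largest transcript count per gene (SE; adjusted p = 0.00246 and 0.0180), and transcript rows called both as well.

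Exact permutation tests on CPM, two-sided and adjusted over 60 tests of 6 genes in 10 comparisons, passed in further cases where the main edgeR fit did not. The 6 genes include the 4 called for any difference in these birds, and edgeR was adjusted over 826 genes. The smallest possible p was 0.00216, and this CPM has no TMM scaling. These passes are therefore not independent support for the calls. CGA was higher at 10Lv than at 8L (3246 against 1405 CPM; adjusted p = 0.00866), and FSHB, CGA and PRL were higher at 12Lv than at 10Lv (adjusted p = 0.00866, 0.00866 and 0.0395). PRL was lower at 12La than at 14La (9840 against 22622 CPM; adjusted p = 0.0395), and POMC was lower at 14La than at 16La (9770 against 18448 CPM; adjusted p = 0.00866). The call of FSHB from 8L to 10Lv was not held (adjusted p = 0.1399).

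Genes called in both comparisons with the 8L birds were counted. FSHB and CGA, 2 genes, were lower at 8L than at 16La and than at 16Lv, where independent lists share 0.00969. The comparisons share the 8L birds, and simulated groups without effect shared 0 genes. The correlation across the 826 genes, which are not independent replicates, was 0.423 against 0.495 simulated without effect, and the covariance 0.713 against 0.942. With the 8L birds split 3 and 3, 0 to 1 genes were shared and the correlation was -0.137 to 0.0504.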

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

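Chosen after their results were seen were the tests with depth or the most abundant genes, the test of other pituitary genes at 12 h, the test of transcript sums and the splits of the birds, since a trial of the splits had been run. The slopes by bird number and the leave-one-out count at 12 h were chosen after the data were seen but before their own results.

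At 12 h of light, relative to 8L, which both arms share, the spring-arm effect exceeded the autumn-arm effect by 2.79 for CGA, 4.55 for FSHB and 4.44 for LOC107319226 on the log2 scale, by the test of 12Lv against 12La. A single library does not account for it, since all 36 of 36 fits of the 3 genes, each without 1 of the 12 birds, stayed past the threshold. A difference in depth as the whole source is argued against too, since with the log2 total as a covariate the highest adjusted p of the 3 genes was 0.00154. Less pituitary tissue in the 12La samples as the whole source would lower other pituitary genes there by about as much as CGA, but the median log2 fold change of POMC, CHGA, CHGB, SCG3 and POU1F1 was -0.33, while matrix genes were higher at 12La as a list, so some more tissue of other kinds there stays open. A hypothesis that stays is that the direction of day length change, or the time and age that go with it, may set these 3 genes at 12 h, which the design does not separate and no test here decides.

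FSHB, CGA, PRL and LOC107319226 were higher with longer days. With the log2 total count as a covariate 4 of the 4 stayed past the threshold in the day length trend, and without the 2 genes with the most counts 4 of the 4 did, which argues against depth or a few abundant genes as the whole source. In 6 sets of 9 birds with the same rank of bird number, 24 of 24 slopes were positive, so the low-detection libraries, most of them in 1 set, do not carry the trend. Day length stays as a hypothesis, examined on the birds in which the trend was found.

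Summed counts varied strongly between birds of a photoperiod, with a common dispersion of 1.32 over the 826 genes. Over the 673 of them with 2 or more transcripts, the median dispersion was 1.99 in the sums and 0.137 for the largest transcript of the same genes, a ratio of 14.5. Over the 153 with 1 transcript the ratio was 1.05. Of the 673 genes, 46 also passed the filter by their largest transcript, and their medians were closer, 0.203 in the sums and 0.0831 for the largest transcript. The ratio of 14.5 thus rests mostly on genes with low largest-transcript counts. Reads entered on every compatible transcript are a candidate source, as these ratios would need. No biological explanation was tested.

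Other flagged values are birds far from the rest of their photoperiod, 5 in 53 groups of values examined where chance gives about 2.65. FSHB was 0 CPM in 14Lv replicate 6, whose nearest neighbour had 152 CPM, and PRL was 4505 CPM in the same bird. CGA was 2070 CPM in 8L replicate 5 and 12789 CPM in 16Lv replicate 2. PRL was 1541 CPM in 12Lv replicate 6. Both 14Lv replicate 6 (9101 counts, 544 genes detected) and 12Lv replicate 6 (18166 counts, 963 genes) are among the 9 libraries with under 2000 genes detected, and they hold 3 of the 5 values.

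Other splits of the birds were drawn for each count of genes, 100 each with the real one included. The share of splits with as many genes was under 0.05 for any difference (4 genes, 2 of 100, highest other 6), 8L against 16La (4 genes, 1 of 100, highest other 1) and 16Lv against 8L (2 genes, 1 of 100, highest other 1). It was also under 0.05 for the day length trend (5 genes, 1 of 100, highest other 4), 12Lv against 12La (3 genes, 2 of 100, highest other 3) and 14La to 12La (3 genes, 1 of 100, highest other 1). These shares are not adjusted over the comparisons, and for any difference a split gave more genes than the real grouping. They do not exclude chance. An earlier draw of 40 splits gave 2 of 40 for 16Lv against 8L, with a highest other count of 6, so the share was not under 0.05 in that draw. A split with several times the real count may point to a structure among these birds other than their photoperiod, and what that split followed was not tested. The share was 0.05 or more for 8L to 10Lv (1 gene, 11 of 100, highest other 1, and 2 of 40 in the earlier draw) and 10Lv to 12Lv (1 gene, 9 of 100, highest other 2). For the comparisons with 0 genes all 100 of 100 splits gave as many, with a highest other count of 4 for the slope difference, 1 for 14 h, 10 h, 10La to 8L and 14Lv to 16Lv, and 0 for 16Lv against 16La, 16La to 14La, 12La to 10La and 12Lv to 14Lv.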

How the results depend on the processing

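The largest transcript counts, the bird rank block, the libraries left out by bird number, detection or in turn, and the exclusion of the 2 genes with the most counts were chosen after seeing the data. Of 494 values of named genes under alternatives, 449 kept their direction and side of the threshold, 27 kept the direction and lost the threshold, 18 gained it and 0 changed sign. Of 45 hormone levels from deposited CPM, 42 moved by less than 1 SD, and of 116 counts of list members 115 stayed within 1.5 times. Median shifts between scalings, computed for the comparisons of end points and the trend only, stayed under 0.1 on the log2 scale. The median log2 fold change of the main fit was itself -0.28 at 16Lv against 16La and -0.27 at 16Lv against 8L. It was -0.008 at 8L against 16La and -0.006 for the trend. Simulated 4-fold changes at 8L against 16La were called for 27.3% of summed genes and 98.7% of largest-transcript genes in the same libraries. The simulations changed 200 of 826 and 105 of 210 genes, so these percentages are not comparable. What depth alone limits was not separated from how reads were counted. The cause of each change below was not tested, except that fits of 12 birds hold fewer birds and that other filters test other numbers of genes.

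Without a filter the counts of genes were 1449 for any difference, 24 for 8L against 16La, 23 for 16Lv against 8L, 32 for 16Lv against 16La, 57 for the trend, 84 for the slope difference, 28 at 14 h, 23 at 12 h and 5 at 10 h. For the steps in order of the cycle they were 10 from 16La, 55 from 14La, 35 from 12La, 2 from 10La, 6 from 8L, 0 from 10Lv, 15 from 12Lv and 19 from 14Lv. DESeq2 called 7 genes for 8L against 16La, 6 for 16Lv against 8L, 1 at 10 h, 3 from 8L to 10Lv, 4 from 10Lv to 12Lv and 1 from 14Lv to 16Lv. RLE scaling gave 1 at 10 h, 2 from 8L to 10Lv and 2 from 10Lv to 12Lv. Fits of 12 birds gave 0 for 16Lv against 8L, 5 at 12 h, 0 from 8L to 10Lv and 0 from 10Lv to 12Lv. Limma on deposited CPM gave 7 for any difference, 1 for 16Lv against 8L, 4 for 16Lv against 16La, 1 from 14La to 12La, 0 from 8L to 10Lv and 0 from 10Lv to 12Lv. The log2 total as a covariate gave 7 for any difference, 7 for 8L against 16La, 1 for the slope difference. Transcript rows gave 5 for 16Lv against 8L, 5 at 12 h, 0 from 8L to 10Lv, 2 from 10Lv to 12Lv and 2 from 12Lv to 14Lv.

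The largest transcript gave 8 for any difference, 5 for 16Lv against 8L, 1 at 10 h, 0 from 8L to 10Lv, 3 from 10Lv to 12Lv and 2 from 12Lv to 14Lv. With a minimum count of 3 as well it gave 18 for any difference, 7 for 8L against 16La, 1 for 16Lv against 16La, 9 for the trend, 2 at 14 h, 8 at 12 h, 7 from 14La to 12La, 0 from 8L to 10Lv and 3 from 10Lv to 12Lv. The bird rank block gave 1 at 10 h, 2 from 8L to 10Lv and 2 from 10Lv to 12Lv. Without the highest-numbered birds 0 genes passed from 8L to 10Lv, and without libraries under 2000 genes 4 passed for 16Lv against 8L and 0 from 8L to 10Lv. Leaving out each library in turn gave 1 to 3 genes for 16Lv against 8L (1 without 8L replicate 1, 2, 3 or 4 or 16Lv replicate 2), 0 to 1 for the slope difference and 0 to 2 from 8L to 10Lv (0 without 8L replicate 1, 2, 3, 4 or 5 or 10Lv replicate 2 or 5). With an estimated correlation 1 list passed for 8L against 16La and 0 for 16Lv against 16La, in place of 2 and 1. With the 8L birds split 3 and 3, between 0 and 1 genes were shared by the comparisons with 8L.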

Other observations

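The tests on the largest transcript count per gene and the correlations below were chosen after the data were seen, that of CGA with FSHB before its own result. With the largest transcript and a minimum count of 3, 1460 genes were tested and NTS, the gene of neurotensin, had a positive slope on day length. NTS averaged 361 ± 270 CPM of largest-transcript counts at 16La and 804 ± 774 at 14La, had 2 counts at 12La and 1 at 10La, 0 of 120730 counts at 8L, and averaged 48.1 ± 52.8 CPM at 10Lv, 230 ± 66.1 at 12Lv, 79.5 ± 71.7 at 14Lv and 163 ± 256 at 16Lv (SD, n = 6 each). Its slope was 0.70 ± 0.11 per hour of light on the log2 scale (SE; adjusted p = 2.22e-05). The slope passed without each of the 54 libraries in turn. The mean of NTS at 14La was 521 ± 386 CPM without 14La replicate 6 (SD, n = 5). At 14 h NTS was lower in the spring arm by -3.30 ± 0.67 (log2 fold change ± SE; adjusted p = 0.0161), and the call was lost without 14Lv replicate 2 or 3 (highest adjusted p = 0.128). At 12 h NTS went the other way, higher in the spring arm by 3.99 ± 1.01 (log2 fold change ± SE; adjusted p = 0.0460). That call was lost in 28 of 54 fits without 1 library (highest adjusted p = 0.282). LOC107323085, a protein-coding locus without a symbol, and TBX20, a T-box transcription factor, were higher on short days, with slopes of -0.55 ± 0.08 and -0.35 ± 0.09 (SE; adjusted p = 1.12e-07 and 0.0283). The call of TBX20 was lost without 16La replicate 2 or 4, 10La replicate 5, 8L replicate 2 or 3, 10Lv replicate 2 or 5 or 16Lv replicate 5 or 6 (highest adjusted p = 0.183). LOC107323085 averaged 8.70 ± 13.5 CPM at 16La, 173 ± 163 at 8L and 10.4 ± 25.4 at 16Lv (SD, n = 6 each).

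In the same fit 0 of 17 genes of protein folding in the endoplasmic reticulum passed at 8L against 16La, and the list was lower by camera (adjusted p = 0.000123, and 0.0902 with an estimated correlation), with HSP90B1 at -1.20 ± 0.46 and PDIA3 at -1.16 ± 0.46 (log2 fold change ± SE). Of the other 9 lists in this fit, the pituitary hormones were lower at 8L than at 16La by camera (adjusted p = 6.82e-11, and 5.71e-05 with an estimated correlation). The camera adjusted p was 0.888 for gonadotroph genes, 0.964 for the clock, 0.418 for matrix genes, 0.888 for immediate early genes, 0.631 for secretory granule genes, 0.159 for steroid and thyroid hormone receptors, 0.168 for oxidative phosphorylation and 0.937 for ribosomal proteins, whose direction was lower here. Among the receptor list, FKBP5, a chaperone partner of steroid receptors, had a log2 fold change of -2.56 ± 1.00 (SE), with an adjusted p of 0.691 over all genes and 0.0444 adjusted over the list alone. At 16Lv against 16La, 3 lists were lower by camera, namely the pituitary hormones and the ribosomal proteins (adjusted p = 0.0369 for both) and protein folding (0.00472), and 0 with an estimated correlation (adjusted p = 0.336, 0.887 and 0.336). For the trend the pituitary hormones and protein folding were higher (adjusted p = 4.21e-15 and 0.00978), and with an estimated correlation the hormones were (adjusted p = 1.38e-06 and 0.323). At 16Lv against 8L the pituitary hormones were higher (adjusted p = 8.07e-07, and 0.00219 with an estimated correlation), but fry did not pass them (adjusted p = 0.0566). In this fit fry passed the hormones and protein folding (adjusted p = 0.0183) at 8L against 16La. It passed protein folding alone at 16Lv against 16La (adjusted p = 0.0414) and the hormones alone for the trend. On summed counts fry passed 1 list, the hormones, in each of these comparisons except 16Lv against 16La, where it passed 0.

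In all, 6 pairs of genes were compared within photoperiods, as deviations of 54 birds from their photoperiod means. The hypothesis that FSHB and CGA vary together among birds of the same photoperiod was not decided, with Pearson r = 0.156 (permutation p = 0.328, adjusted p = 0.493) and Spearman rho = 0.170 (permutation p = 0.262, adjusted p = 0.393), and r = 0.193 without the 2 farthest birds and 0.299 in the 45 birds with 2000 or more genes detected. PRL and POMC deviated together, with r = 0.710 and rho = 0.691 (permutation p = 1e-05 for both, the smallest that 100000 permutations give, adjusted p = 6e-05). The r was 0.654 without the 2 farthest birds and 0.632 in those 45 birds, and the median r of PRL with all tested genes was 0.202.

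The 9 birds with the highest number of their photoperiod deviated together, with a mean r across genes of 0.282 against at most 0.102 among birds of any other rank (permutation p = 0.0001, one-sided, the smallest that 9999 permutations give). This rank was chosen after its low detection was seen, and p is not adjusted over ranks. Most libraries with under 2000 genes detected are among these birds, so the correlation is not separated from low detection. ACOT9 took 49.3% ± 8.26 of their summed counts and 15.6% ± 4.80 of their largest-transcript counts (SD, n = 9).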
